A study of Homo sapiens with 6 samples.

How the data were processed

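RNA levels were measured with single-colour Affymetrix Human U133 Plus arrays in MV4;11 cells, a human acute myeloid leukaemia line that carries the MLL-AF4 fusion. Per the labels' protocols, cells were plated in 12-well format in triplicate, kept for 3 h with either the solvent DMSO or 25 nM CA, which the series title gives as cortistatin A, and then washed and frozen. RNA was isolated with a Qiagen column kit or with TRIzol, and biotinylated cRNA was made with a 3' in vitro transcription kit, per the labels' protocols. Which of the 6 arrays used which isolation is not given in the sources used here, so the isolation could not be tested as a batch. The groups were taken from the treatment label, with 3 DMSO arrays and 3 cortistatin A arrays.

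The deposited table holds 1 value per probe set and array, on the log2 scale, and the submitters' processing notes name RMA and the affy package with no version. The table does not state its scale. The values were taken as log2 because RMA returns log2 values and because they lay between 0.81 and 13.84. RMA in its usual form subtracts background, makes the intensity distributions of all arrays alike by quantile normalization and summarises the probes of a probe set. With such values a shift of all transcripts in one direction would be removed, and small changes near the background are compressed. Scanner files, detection calls and scan dates were not used here. The array medians were 3.74 to 3.77. No sequencing depth applies, and the number of arrays limits the precision.

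The table has 54675 probe sets, of which 62 are controls. Among the others, 41091 name 1 gene in the platform annotation, 1801 name several and 11721 are not named in the annotation used here. Symbols were updated through the gene identifiers of the RefSeq table for 41037 of the single-gene probe sets, and 54 kept the platform symbol. For each gene the single-gene probe set with the highest mean over the 6 arrays was used, which gave 19775 genes, 10523 of them with more than 1 probe set. No genome build is named, so no coordinates are given, and the gene identity rests on the platform annotation.

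Cortistatin A and DMSO arrays were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend or robust variances, group as the only term, two-sided, Benjamini-Hochberg adjusted p under 0.05). All 6 arrays entered the fit, with 4 residual and 2.68 prior degrees of freedom. No filter on dim genes and no fold threshold was applied. Log2 changes are cortistatin A minus DMSO and errors are limma standard errors unless SD is written. A total of 33 gene lists with 620 genes, 552 of them measured, were tested as sets against the other genes with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. Single contrasts between control probe sets were tested with a two-sided exact permutation test, for which 3 against 3 arrays allow no p below 0.1.

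The genes named in the text were the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, the 4 regulators CEBPA, IRF8, IRF1 and ETV6 that the study is known to have named, the drug targets CDK8 and CDK19 with their cyclin CCNC, and up to 4 members with the smallest p of each list described. The groups, the gene test, the lists, this rule and the alternatives were fixed before the data were examined, except that the fit with a 3' to 5' control index as a covariate, the receptor genes and the FOXO list were chosen after results had been seen.

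The alternatives were the replicate number as a block, dim genes left out (mean at or below the median of all probe sets), the mean of all probe sets of a gene, probe sets without the cross-hybridising types (_x_at and _s_at), a further quantile normalization, arrays centred on the housekeeping list, trend and robust variances, each array left out in turn, a fold of at least 1.2, an adjusted p under 0.1, all probe sets tested as such, an equal-variance two-sample test per gene without moderation, camera with an estimated correlation, and fry. Housekeeping centring subtracted from each array the median level of the measured housekeeping genes on it, relative to the mean of these medians. The covariate was the mean 3' minus 5' log2 signal of all control transcripts on each array. No 2 arrays were alike enough to be one array deposited again, since at most 678 values were identical in a pair.

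The gene and list steps were each tested on simulated data in 10 simulations of the 6 arrays and 19775 genes. For the gene step 200 genes were changed in each simulation, and for the list step only the 20 genes of 1 list. The genes to change were drawn from those above the median of all values, so the rates do not cover dim genes. The gene step recovered 11.8% of 1.2-fold, 70.4% of 1.5-fold and 92.4% of 2-fold changes, with 4.44% of its calls false. Camera called a list of 20 genes shifted by 0.15 in 10 of 10 simulations, and camera with an estimated correlation called it in 3. At the preset correlation 1 list without a shift was called over all simulations. The simulated genes varied independently of each other, so the simulations cannot show whether the preset correlation holds for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.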

Results

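Expression profiles were collected from MV4;11 cells, an acute myeloid leukaemia line with the MLL-AF4 fusion, after 3 h in DMSO (3 arrays) or in 25 nM cortistatin A (3 arrays). Cortistatin A is a steroidal alkaloid that inhibits CDK8 and CDK19, the kinases of the Mediator complex. Deposited log2 RMA values of 19775 genes were compared. Pairs of arrays correlated across genes at r = 0.9962 to 0.9966 within the DMSO group, 0.9965 to 0.9969 within the cortistatin A group and 0.9954 to 0.9965 between the groups. The labels describe wells plated in triplicate and do not say that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

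The comparison asked which transcripts differ early after the Mediator kinases are inhibited. Between the cortistatin A and DMSO arrays 115 genes differed, 88 of them higher and 27 lower with the drug (76.5% higher), by limma at an adjusted p under 0.05. The sizes were small, with a median rise of 0.51 on the log2 scale (1.42-fold) and a median fall of 1.40-fold. Of the higher genes 28 reached 1.5-fold and 2 reached 2-fold, and of the lower genes 6 reached 1.5-fold and 0 reached 2-fold. The smallest change called was 1.26-fold, and 111 of the 115 genes had a mean above the median of all probe sets. The groups did not overlap for any of the 115 genes, nor for 19.4% of all genes, where chance gives 10%. At an unadjusted limma p under 0.05 there were 2499 genes, 1346 higher and 1153 lower. With arrays centred on housekeeping genes the split of the calls was 115 higher and 12 lower (90.6% higher). That centring moved the median change of the housekeeping list itself from 0.0019 to 0.062, so it did not hold these genes level. The more uneven split may come from this shift, and the signs, medians and calls that turn with this centring below carry the same limit.

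BHLHE40, a basic helix-loop-helix repressor, had the largest rise with the brightest probe set per gene, 1.21 ± 0.07 on the log2 scale or 2.31-fold (limma adjusted p = 0.00433, n = 3 arrays per group). Its other probe set above the array median gave 0.06. ALDH1A3, which oxidises retinaldehyde to retinoic acid, rose by 1.10 ± 0.06 (limma adjusted p = 0.00433), or 2.14-fold. The other probe set of ALDH1A3 was dim (mean at or below the median of all probe sets). With the mean of all probe sets of a gene the rises of BHLHE40 and ALDH1A3 were 0.63 and 0.55 and still passed. There CCR6 (0.996) and GPR183 (0.92) rose more, so the first rank of BHLHE40 rests on the probe set chosen. CCR6, a chemokine receptor, rose by 0.996 ± 0.109 (limma adjusted p = 0.0248). INHBA, a subunit of activin and inhibin, rose by 0.97 ± 0.09 (limma adjusted p = 0.0198). Its other bright probe set, used without the _x_at and _s_at types, gave 1.43 (limma adjusted p = 0.0301). GPR183, an oxysterol receptor, rose 1.90-fold, and TIFAB, a relative of the signalling adaptor TIFA, rose 1.84-fold. FAM43A rose by 0.80, the cytokine receptor chain IL7R by 0.76 and ID2, an inhibitor of helix-loop-helix factors, by 0.73. CD180, a relative of the Toll-like receptors, rose by 0.73, the monocyte chemokine receptor CCR2 by 0.72 and the prostaglandin receptor PTGER4 by 0.71. These 6 genes had limma adjusted p from 0.00838 to 0.0248. For FAM43A and PTGER4 a further bright probe set gave -0.12 and -0.02. With the mean of all probe sets neither was called (0.34 and 0.35, limma adjusted p = 0.102 and 0.165). Over all alternatives the adjusted p was 3.7e-07 to 0.683 for FAM43A and 8.3e-09 to 0.683 for PTGER4.

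TXNIP, the thioredoxin-interacting protein, had the largest fall and dropped by 0.95 ± 0.05 on the log2 scale, or 1.93-fold (limma adjusted p = 0.00433, n = 3 arrays per group). Both of its other bright probe sets were lower as well. SERTAD1, a regulator of cell-cycle transcription, fell by 0.69 ± 0.07 (limma adjusted p = 0.0198). HEXIM1, the inhibitor of the elongation kinase P-TEFb, fell by 0.60 ± 0.08 (limma adjusted p = 0.0417), or 1.52-fold. The atypical E2F repressors E2F8 and E2F7 fell by 0.54 and fell by 0.51 (limma adjusted p = 0.0206 and 0.0198). CCNG2, an unconventional cyclin, fell by 0.54 (limma adjusted p = 0.0198), with 4 other bright probe sets between -0.49 and 0.20. The ubiquitin ligase subunit FBXO32 (-0.66), the noncoding antisense transcript BAZ2B-AS1 (-0.64) and PELI1, a ubiquitin ligase of innate immune signalling (-0.63), fell as well. So did PPP1R10, a nuclear regulator of protein phosphatase (-0.56), the homeobox factor HOXC6 (-0.55) and INTS6L, a relative of an Integrator subunit (-0.53). These 6 genes had limma adjusted p from 0.0124 to 0.0487. With the mean of all probe sets of a gene the calls of FBXO32 (-0.14), PELI1 (-0.27), CCNG2 (-0.34) and E2F7 (-0.31) ended, with limma adjusted p from 0.123 to 0.436. The other probe sets of FBXO32, PELI1 and E2F7 were all dim, so their means average in dim probe sets. FBXO32 lay below the median of all probe sets, and its call also ended with housekeeping centring, with a further quantile normalization and without the _x_at and _s_at types. In the last of these FBXO32 kept its probe set and its change (-0.66, limma adjusted p = 0.0604). HEXIM1 was not called without the _x_at and _s_at types, whose removal left only a dim probe set, at -0.06. Its other bright probe set, of the _s_at type, was at -0.60. Nor was HEXIM1 called with housekeeping centring (-0.54), which ended the call of INTS6L (-0.47) as well. Over its 14 alternatives the limma adjusted p of HEXIM1 was 4.6e-05 to 0.844.

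The number of genes called rested on all 6 arrays. Without DMSO replicate 1, DMSO replicate 2, cortistatin A replicate 1 or cortistatin A replicate 3 limma called 0 genes, while 1952, 2342, 2137 and 2312 passed an unadjusted p of 0.05. It called 4 genes without DMSO replicate 3 and 3 without cortistatin A replicate 2. All 115 genes kept their sign and an unadjusted p under 0.05 in these 6 fits. Neither is independent support. The groups did not overlap for these genes, so leaving out 1 array could not turn a sign, and the genes had been selected on the same arrays. The 3' minus 5' signal of the beta-actin control probe sets, a measure of transcript length in the labelled RNA, was 1.75 ± 0.06 in DMSO and 1.95 ± 0.11 in cortistatin A (SD, n = 3). The groups did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). For each of the other single control transcripts they overlapped. With the 3' to 5' index of all control transcripts as a covariate limma called 0 genes, and 1264 passed an unadjusted p of 0.05. The index itself did not overlap between the groups (1.58 to 1.64 in DMSO and 1.66 to 1.70 in cortistatin A), so the covariate and the group share most of their spread. The median standard error of the 115 genes went from 0.055 to 0.109 there, and the median ratio of their changes to those without the covariate was 1.003.

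**Figure D1:**
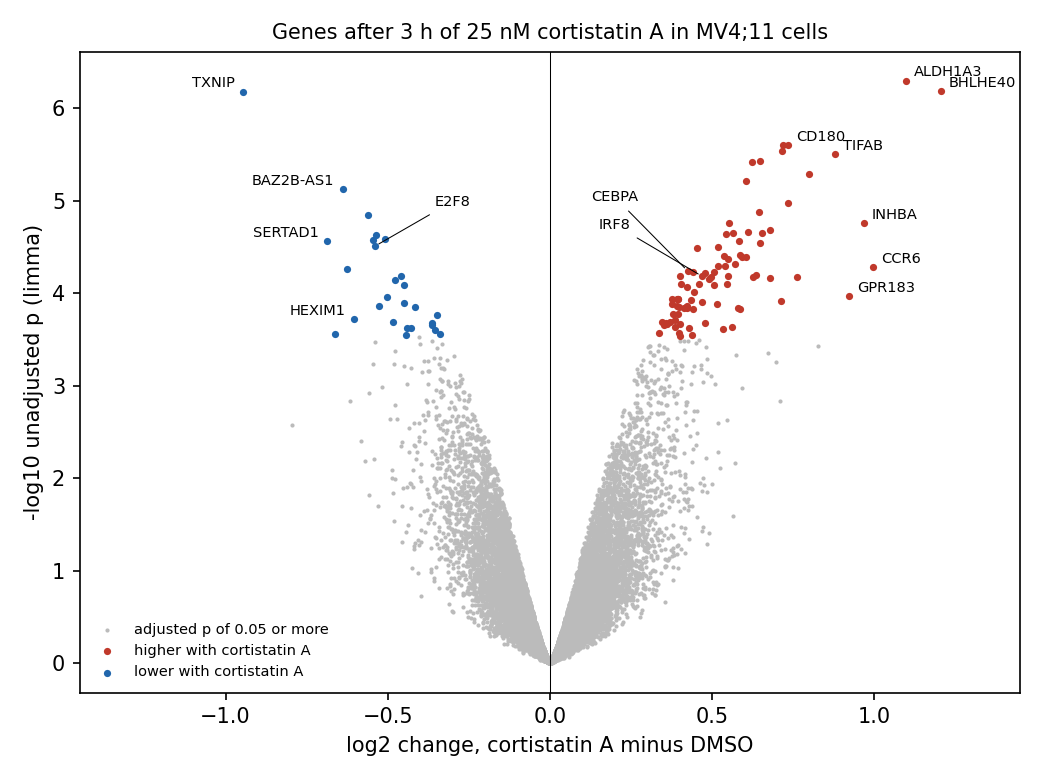
Each point is 1 of 19775 genes, with the log2 change (cortistatin A minus DMSO) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; red marks the 88 higher and blue the 27 lower genes at an adjusted p under 0.05, and grey the rest. BHLHE40 and ALDH1A3 lie farthest to the right and TXNIP farthest to the left among the genes called.

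**Figure D2:**
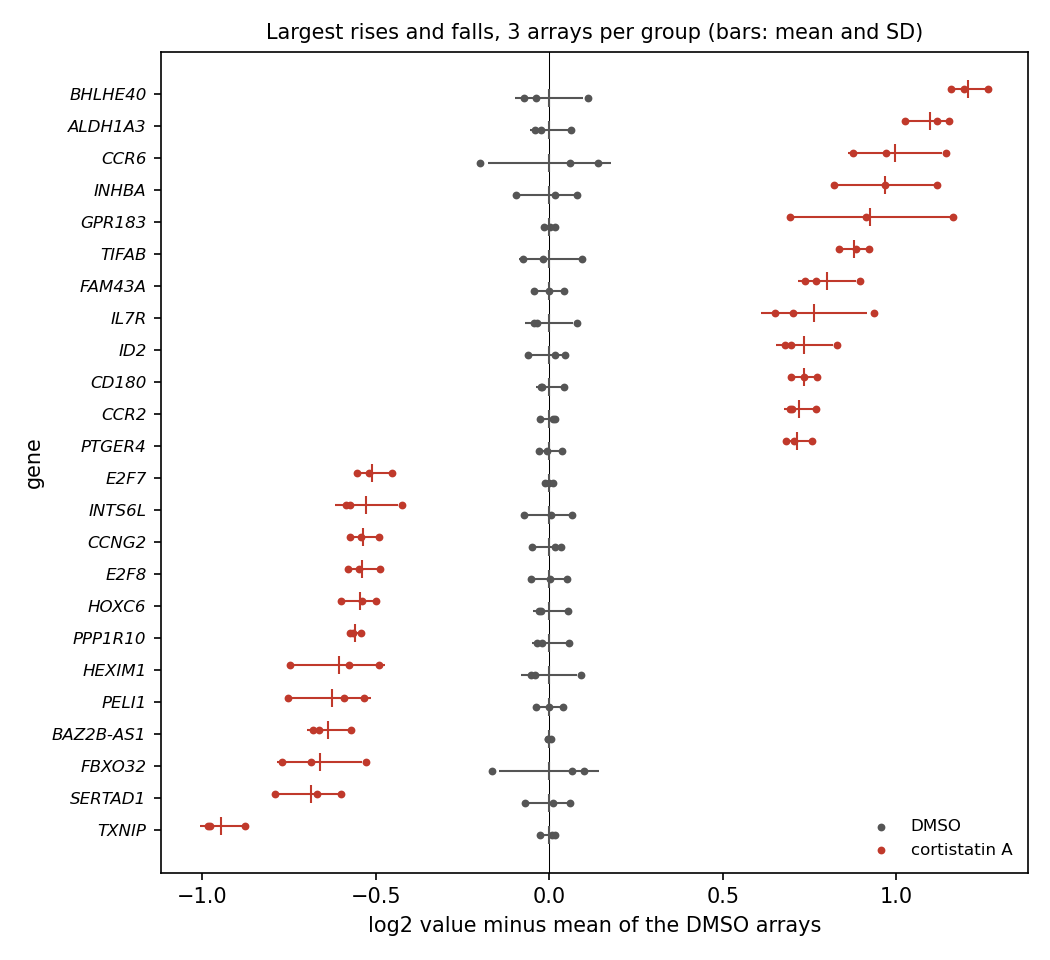
Each point is 1 array, shown as the log2 value minus the mean of the 3 DMSO arrays (horizontal axis) for the 12 largest rises and the 12 largest falls called (vertical axis); grey is DMSO, red is cortistatin A, and bars give the mean and SD. For every gene shown the 3 cortistatin A arrays lie on one side of the 3 DMSO arrays, from 1.21 for BHLHE40 to -0.95 for TXNIP on average.

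The transcripts of the drug's own targets did not pass the test. CDK8 differed by -0.05 ± 0.07 (limma adjusted p = 0.824), CDK19 by -0.22 ± 0.07 (limma adjusted p = 0.249) and their cyclin CCNC by 0.03 ± 0.05 (limma adjusted p = 0.839). The sign of the CDK8 value turned with housekeeping centring (0.011), with the 3' to 5' index (0.047) and without cortistatin A replicate 2 (0.012), and that of CCNC with the mean of its probe sets (-0.068). The other probe set of CCNC was dim. CDK19 was called with trend and robust variances (limma adjusted p = 0.0339, range over its alternatives 0.0339 to 0.893). Among 7 genes of the Mediator kinase module 0 passed over all genes or adjusted over the list alone (median -0.03, camera adjusted p = 0.686), and likewise 0 of 24 core Mediator genes (median -0.03, camera adjusted p = 0.630), and both medians turned to 0.03 with housekeeping centring.

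Of the 4 regulators named by the study, the myeloid master regulator CEBPA rose by 0.42 ± 0.05 (limma adjusted p = 0.0248, n = 3 arrays per group), or 1.34-fold. The interferon regulatory factor IRF8 rose by 0.47 ± 0.05 (limma adjusted p = 0.0248), or 1.38-fold. IRF1 (0.15 ± 0.06, limma adjusted p = 0.395) and ETV6 (0.15 ± 0.05, limma adjusted p = 0.326) did not pass over all genes. Adjusted over the list alone all 4 passed, and the list was higher as a set (camera adjusted p = 7.2e-05; adjusted p = 0.190 with an estimated correlation). The study may have chosen these genes on the same samples, so neither result is independent evidence of their direction.

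Of the 33 lists, camera called 10, with 8 higher and 2 lower, and 5 of these were still called with the 3' to 5' index as a covariate. With an estimated correlation 0 lists were called, 5 had an unadjusted p under 0.05, and fry called 10, of which 7 were among those of camera. Myeloid transcription factors were higher as a set (20 measured, median 0.15, camera adjusted p = 7.2e-05; adjusted p = 0.466 with an estimated correlation). The list holds CEBPA, IRF8, IRF1 and ETV6, the regulators named by the study, so its result is in part the same result and not independent of it. ID2, CEBPA and IRF8 rose over all genes, and 9 members, 8 higher and 1 lower, passed adjusted over the list alone. CEBPD stood at 0.34 (limma adjusted p = 0.0689) and the zinc finger factor EGR1 at -0.54 (limma adjusted p = 0.0720). Monocyte and macrophage markers were higher as a set (27 measured, median 0.10, camera adjusted p = 0.000376; adjusted p = 0.168 with an estimated correlation). CCR2 rose over all genes, and 4 members, all higher, passed adjusted over the list alone. The lipopolysaccharide receptor TLR4 was at 0.43 and the Fc receptor genes FCGR2A and FCER1G at 0.21 and 0.20, which passed over the list alone but not over all genes. FCGR2A and FCER1G were at 0.038 and 0.12 with the mean of their probe sets, and without the _x_at and _s_at types CEBPD was at 0.15 and TLR4 at 0.23. The other probe set of FCGR2A and that of CEBPD were dim. Granulocyte granule genes were not called (15 measured, camera adjusted p = 0.630), with 0 members past the threshold over all genes and 2, both lower, adjusted over the list alone. The difference between these lists was not tested.

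Genes of cytokine receptors were higher as a set (25 measured, median 0.09, camera adjusted p = 0.00184; adjusted p = 0.304 with an estimated correlation). The stem cell factor receptor KIT rose by 0.54 (limma adjusted p = 0.0227) and the chemokine receptor CXCR4 by 0.39 (limma adjusted p = 0.0442), and 9 members, 7 higher and 2 lower, passed adjusted over the list alone. The set was not called with the 3' to 5' index as a covariate (camera adjusted p = 0.155) or without the _x_at and _s_at types (camera adjusted p = 0.143, range over the alternatives 5.8e-05 to 0.304), where CXCR4 was not called either. Without those types CXCR4 kept its probe set and change, while KIT, whose only single-gene probe set is of the _s_at type, was not measured. Targets of the MLL fusion and progenitor genes were higher as a set (15 of 25 members measured, median 0.09, camera adjusted p = 0.00367, and 0.190 with an estimated correlation). The result covers the measured members only. Over all genes 0 members passed, and adjusted over the list alone 7 did, 6 higher and 1 lower. RUNX2 (0.34), LMO2 (0.31) and MEF2C (0.47), 3 haematopoietic transcriptional regulators, stood opposite the receptor kinase FLT3 (-0.20). RUNX2 was at 0.097 and MEF2C at 0.31 with the mean of their probe sets, and the other bright probe set of RUNX2 was at -0.057. This call also ended with the index as a covariate (camera adjusted p = 0.0671, range over the alternatives 4.8e-05 to 0.190).

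The endoplasmic reticulum and amino acid stress list was higher as a set (20 measured, median 0.13, camera adjusted p = 3.8e-05; adjusted p = 0.168 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 6 did, all higher. Its members with the smallest p were SLC7A11, the cystine transporter (0.83, limma adjusted p = 0.0569), HERPUD1 of the endoplasmic reticulum degradation pathway (0.35), the lipoprotein receptor VLDLR (0.36) and the pseudokinase TRIB3 (0.28). SLC7A11 was at 0.50 and passed with the mean of its probe sets (limma adjusted p = 0.0479), and without the _x_at and _s_at types HERPUD1 was at 0.12. The other probe set of HERPUD1 was dim. The list of MYC and ribosome biogenesis genes was higher as a set (19 measured, median 0.06, camera adjusted p = 0.00184; adjusted p = 0.466 with an estimated correlation). MYC itself rose by 0.39 (limma adjusted p = 0.0332), 3 members, all higher, passed adjusted over the list alone, and POLR1B, NOP16 and RRP9 were at 0.22, 0.19 and 0.20. POLR1B was at 0.11 with the mean of its probe sets, and the other bright probe sets of NOP16 lay between -0.054 and 0.34. That call ended without the _x_at and _s_at types (camera adjusted p = 0.0589, range over the alternatives 1.6e-05 to 0.466). MYC, whose only single-gene probe set is of the _s_at type, was not measured in that alternative. Hypoxia and glycolysis genes were higher as a set by a narrow margin (24 measured, median 0.06, camera adjusted p = 0.0404; adjusted p = 0.466 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Those with the smallest p were NDRG1 (0.23), VEGFA (0.21), HK2 (0.19) and ADM, which lay near the floor of the arrays with a mean of 2.35 in DMSO. VEGFA was at 0.043 and HK2 at 0.11 with the mean of their probe sets, and a further bright probe set of VEGFA was at -0.16. The hypoxia call ended with the index as a covariate (camera adjusted p = 0.188), with fry, with dim genes left out, with the mean of probe sets and without the _x_at and _s_at types (range over the alternatives 0.0135 to 0.599). It also ended without DMSO replicate 1, 2 or 3 or cortistatin A replicate 1 or 3 (camera adjusted p from 0.0595 to 0.164).

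The genes of S phase were lower as a set (21 measured, median -0.02, camera adjusted p = 0.0308; adjusted p = 0.700 with an estimated correlation). No member passed over all genes or adjusted over the list alone. E2F2 (-0.28), the replication cyclin CCNE2 (-0.31), the ribonucleotide reductase subunit RRM2 (-0.19) and UHRF1 (-0.15) had the smallest p. E2F2 was at -0.13 with the mean of its probe sets, where CCNE2 was at -0.46 and passed (limma adjusted p = 0.0277). With housekeeping centring the median turned to 0.04 and the call ended (camera adjusted p = 0.181). The call also ended with fry, with the index as a covariate (range over the alternatives 0.0041 to 0.714) and without DMSO replicate 1 or 2 or cortistatin A replicate 1 or 2 (camera adjusted p from 0.0572 to 0.133). BET proteins and elongation factors were lower as a set (17 measured, median -0.07, camera adjusted p = 0.0362; adjusted p = 0.652 with an estimated correlation). HEXIM1 fell over all genes, and 1 member higher and 2 lower passed adjusted over the list alone. BRD2 was at -0.39, the elongation factor ELL2 at 0.44 and BRD3 at -0.16. Over all genes BRD2 passed in 3 of its 13 alternatives, ELL2 in 3 of 14 and BRD3, which ranged from -0.20 to -0.10, in 1 of 14. This list was not called with fry, the index, housekeeping centring, dim genes left out, the mean of probe sets or without the _x_at and _s_at types (range over the alternatives 0.0135 to 0.935). Nor was it called without DMSO replicate 1 or 3 or cortistatin A replicate 2 (camera adjusted p from 0.0836 to 0.202). Without the _x_at and _s_at types HEXIM1 entered the list with a dim probe set, at -0.06.

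**Figure D3:**
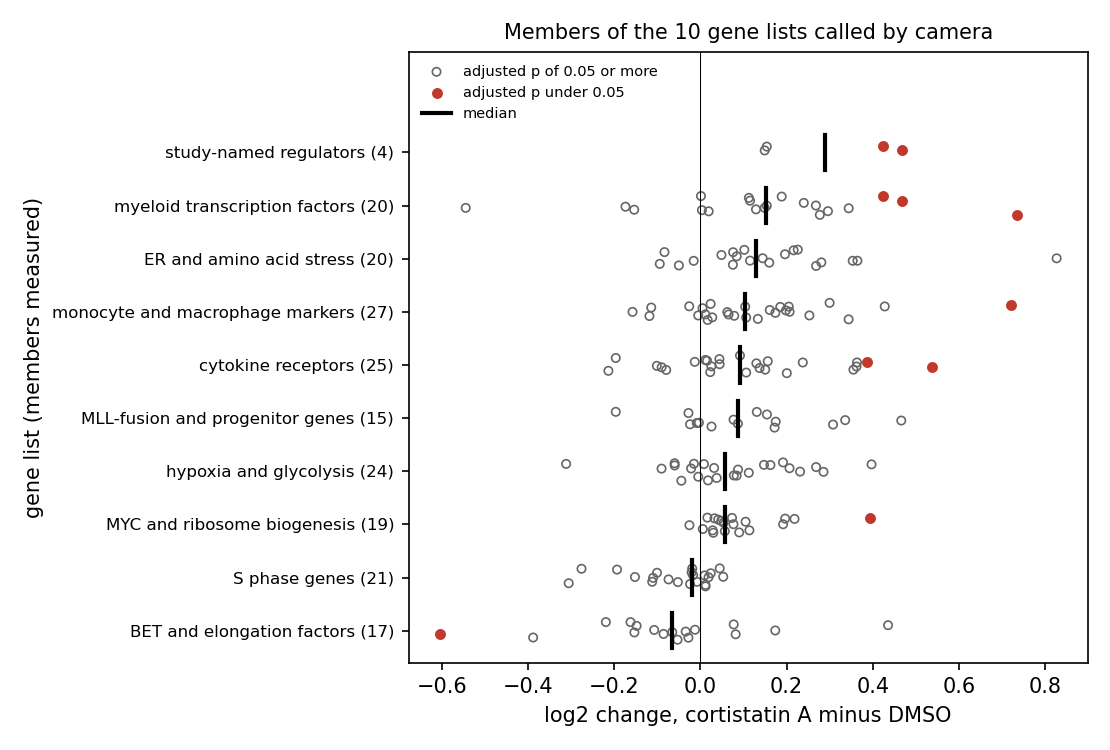
Log2 change (cortistatin A minus DMSO, horizontal axis) of each measured member of the 10 lists called by camera (vertical axis), with filled points for an adjusted p under 0.05 over all genes and a black bar for the median. Medians run from 0.29 for the study-named regulators to -0.07 for BET and elongation factors, and that of the S phase genes, -0.02, turned to 0.04 with housekeeping centring. That centring moved the median of the housekeeping list itself to 0.06.

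Some lists that were not called held single genes that passed. Among targets of TGF-beta signalling (17 measured, camera adjusted p = 0.119; 4 members, all higher, adjusted over the list alone) BHLHE40, ID2 and LDLRAD4 rose, the last by 0.68 ± 0.08 (limma adjusted p = 0.0248). LDLRAD4 was not called with the mean of its probe sets (0.34, limma adjusted p = 0.0673, range over its alternatives 2.0e-05 to 0.683). In the sterol and lipid synthesis list (19 measured, camera adjusted p = 0.0612; 4 members, all higher, adjusted over the list alone) the demethylating enzyme MSMO1 rose by 0.64 (limma adjusted p = 0.0187) and the sterol sensor INSIG1 by 0.40 (limma adjusted p = 0.0499). As sets these lists passed in some alternatives, TGF-beta targets in 3 of 16 (camera or fry adjusted p 0.0041 to 0.935) and the sterol list in 6 of 16 (0.0041 to 0.466). Among STAT5 targets (14 measured, camera adjusted p = 0.586) the kinase PIM1 rose by 0.59 (limma adjusted p = 0.0341) and the signalling suppressor CISH by 0.40 (limma adjusted p = 0.0480), and 2 members passed adjusted over the list alone. The phosphatase gene DUSP6 rose by 0.52 (limma adjusted p = 0.0248) among the ERK feedback genes (16 measured, camera adjusted p = 0.970), where SPRED2 and ETV5 were at -0.28 and -0.24 (-0.12 and -0.14 with the mean of their probe sets). Adjusted over that list alone 3 members were higher and 3 lower. The other probe sets of SPRED2 were dim. Among immediate early genes (27 measured, camera adjusted p = 0.970) MYC and DUSP2 (0.36, limma adjusted p = 0.0430) rose. ZFP36 (-0.40, limma adjusted p = 0.0510) and EGR1 (-0.54, limma adjusted p = 0.0720) did not pass over all genes, and adjusted over the list alone 2 members were higher and 3 lower. In the BCL2 family (13 measured, camera adjusted p = 0.580; 3 members higher and 1 lower adjusted over the list alone) the proapoptotic gene PMAIP1 rose by 0.36 (limma adjusted p = 0.0427), and the lower member was MCL1 (-0.16, limma adjusted p = 0.249 over all genes). The 4 other bright probe sets of MCL1 lay between -0.31 and -0.025. The calls of DUSP2 and INSIG1 ended without the _x_at and _s_at types, that of CISH after a further quantile normalization and that of PMAIP1 with the mean of its probe sets (limma adjusted p from 0.0534 to 0.0761). Without those types DUSP2 and INSIG1 kept their probe sets and changes, and only the genes tested and the moderated variances differed.

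In the other lists 0 members passed over all genes tested. Camera gave adjusted p = 0.149 for antigen presentation (16 measured, median 0.05) and 0.107 for heat shock genes (10 measured, median -0.05, which turned to 0.0063 with housekeeping centring). In both lists 0 members passed adjusted over the list alone. The adjusted p of camera was 0.970 for each of the interferon response (34 measured), NF-kB target and chemokine (25), Wnt target (14), p53 target (21), mitosis (20), oxidative phosphorylation (21), ribosomal protein (10) and housekeeping (11) lists. Of these, 2 interferon response genes (1 higher, 1 lower), 3 NF-kB targets (1 higher, 2 lower) and 1 p53 target (lower) passed adjusted over the list alone, and 0 members of the rest. Markers of other cell types did not stand apart from the other genes, with camera adjusted p = 0.970 for erythroid and megakaryocyte, T and NK cell and B cell markers and 0.851 for stromal and epithelial markers. Their median levels in DMSO were 3.83, 3.85, 3.78 and 3.22, near or below the median of all probe sets, 3.74. At such levels these lists could hardly have shown a change, so nothing follows about the cell types affected. The same limit holds for the Wnt targets, whose median level in DMSO was 3.79. The median, mean and camera direction differed in sign for the granulocyte, interferon, ERK feedback, oxidative phosphorylation, ribosomal protein, housekeeping, T and NK cell and B cell lists.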

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

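The test of the bacterial control transcripts was chosen only after the 3' to 5' signals had been seen, and so was the fit with the 3' to 5' index; the splits of the arrays and the tests of the index slope and of further probe sets were set down before their results.

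A contrast of control probe sets, which the main gene comparison did not use, separated the groups for beta-actin alone among the single control transcripts examined. Chance separates 3 against 3 arrays in 10% of such contrasts, so with several examined the separation may be chance. The hybridisation controls averaged 11.00 on DMSO replicate 3 and 10.40 to 10.58 on the other arrays. The 3' minus 5' log2 signal of beta-actin was higher by 0.201 (SE 0.071) in cortistatin A, with no overlap of the groups, while GAPDH differed by 0.05 (two-sided exact permutation p = 0.3). The bacterial transcripts that the labelling kit protocol adds after RNA extraction differed by 0.041 (SE 0.041) on average. Of these, dap, thr and lys differed by 0.10, 0.12 and 0.03 and phe by -0.08, each with overlapping groups. The bacterial shift was below that of the cell transcripts by 0.086 (SE 0.063). That error treats the shifts as independent, though both were read on the same arrays. Degraded RNA in the treated cells and a difference in labelling therefore cannot be told apart with 3 arrays per group. A labelling difference that also set the gene changes would make genes that follow the index within groups the ones that rose in cortistatin A, and that correlation across genes was r = 0.046 (one-sided exact permutation p = 0.306 over 36 reorderings; genes are not independent replicates), which leaves it open. An effect of the drug on the beta-actin transcript itself is also open and was not tested.

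The 115 genes called in the real grouping compare with 0 in each of the 9 other ways to split the 6 arrays into 3 and 3, and the 10 lists with 0, so 1 of the 10 splits gave as many in each case. With 10 splits the share cannot fall under 0.05. At an unadjusted limma p under 0.05 the real grouping had 2499 genes and the highest of the other splits 1125. Each of the 9 other splits has DMSO and cortistatin A arrays on both sides. Any difference between the treatments therefore widens the spread within the sides and lowers the calls, so these contrasts do not decide about chance. As to direction only, artefacts of single probe sets are argued against for the 61 changed genes with a further probe set above the array median, taken as a set. The brightest further probe set moved the same way in 56 of them (91.8%, exact 95% interval 81.9 to 97.3), against 64.3% of the 5851 genes not called. The interval treats genes as independent, though all were read on the same 6 arrays. Whether probe sets of a gene share probe sequence was not tested. BHLHE40 counted as the same way at 0.06 against 1.21, and the median ratio of the further to the main change was 0.86. The brightest further probe set moved the other way for FAM43A, HECA, LDLRAD4, PTGER4 and VSIR, and a less bright one did so for CCNG2. An effect of cortistatin A on the other genes stays open beside the labelling difference above.

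Among all 54613 probe sets tested one by one limma called 28, and 2 of them have no gene named here. One was higher by 1.49 ± 0.09 on the log2 scale (limma adjusted p = 0.0122), but its DMSO mean of 3.28 lay below the median of all probe sets, 3.74, where it is not shown to be above background, so the size is uncertain. The other fell by 0.76 ± 0.07 (limma adjusted p = 0.0379, n = 3 arrays per group for both).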

How the results depend on the processing

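The fit with the 3' to 5' index was chosen after seeing the data, and all other alternatives were planned. Against 115 genes (88 higher, 27 lower), limma called 321 (212 and 109) with dim genes left out, 762 (455 and 307) with trend and robust variances, 260 (181 and 79) at an adjusted p under 0.1, 76 (58 and 18) with the mean of probe sets, 54 (43 and 11) without _x_at and _s_at types, 28 (20 and 8) over all probe sets, and 0 with the index. Housekeeping centring, which moved the median of the housekeeping list itself to 0.062, gave 115 higher and 12 lower. The test without moderation gave 27 (19 and 8). A further quantile normalization gave 138, and a fold of at least 1.2 gave 115. Leaving out each array gave 0 to 4 genes (0 to 3 higher, 0 to 1 lower). Leaving out dim genes tested fewer genes and also changed the moderated variances (median standard error 0.048 over the 111 changed genes left in, against 0.055 over all 115). The index did not overlap between the groups (1.58 to 1.64 in DMSO, 1.66 to 1.70 in cortistatin A), and with it the median standard error of the 115 genes was 0.109, against 0.061 with the replicate block, while the changes had a median ratio of 1.003 to those without it. The cause of the other differences was not tested.

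The shared replicate numbers did not pair the arrays, since same-numbered arrays correlated at -0.05 to 0.02 in their deviations and 0 of 3 matched their own number best. With the number as a block limma called 0 genes (0 higher, 0 lower; 2243 at an unadjusted p under 0.05, smallest adjusted p = 0.113) and camera all 10 lists.

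Camera called 10 lists (8 higher, 2 lower). It called 6 (5 higher, 1 lower) without _x_at and _s_at types, 6 (0 lower) with the index, 8 (0 lower) with housekeeping centring, 9 (1 lower) with dim genes left out or with the mean of probe sets, 11 after a further quantile normalization, 13 with trend and robust variances, and 7 to 9 without each array (7 to 9 higher, 0 to 2 lower). With an estimated correlation 0 were called (0 higher, 0 lower), with 5 at an unadjusted p under 0.05, and fry called 10 (0 lower), 7 of them shared with camera. The direction that camera gave relative to the other genes, and that of fry, which tests a set by itself, were kept for all 10 in every alternative, but with housekeeping centring the mean of the S phase genes was close to 0 (-0.00066) and their median turned to 0.04. Of the 23 lists not called, 17 turned direction in some alternative (smallest adjusted p there 0.410) and 4 passed in some alternative, none of them doing both in 1 fit. TGF-beta targets passed with dim genes left out, trend and robust variances and fry (adjusted p = 0.00969, 0.0041 and 0.00528), and sterol and lipid synthesis genes with the mean of probe sets, a further quantile normalization, trend and robust variances, the index, fry and without cortistatin A replicate 2 (adjusted p = 0.0041 to 0.0473). The BCL2 family passed with fry (adjusted p = 0.0365) and heat shock genes, lower, with trend and robust variances (adjusted p = 0.0344).

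Signs turned for CDK8 (0.011 with housekeeping centring, 0.047 with the index, and -0.11 to 0.012 without each array, the last without cortistatin A replicate 2), for CCNC (-0.068 with the mean of probe sets), and for TGFBR1 (-0.23) and SC5D (-0.016) without _x_at and _s_at types, which exchanges the probe set; these 4 genes had not been called. The other probe set of CCNC and that of SC5D were dim. Few dim genes were called, and 111 of the 115 genes lay above the array median.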

Other observations

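The receptor genes were picked out after the list of changed genes had been seen, and so were the genes named here and the FOXO list, whose test was set down before its result.

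Several of the higher genes code for G protein-coupled receptors. Among 76 genes above the array median with symbols of such receptor families, which include receptors of many tissues, 9 rose and 0 fell. The 9 were the chemokine receptors CCR1 (0.60), CCR2, CCR6 and CXCR4, the nucleotide and adenosine receptors P2RY2 (0.56), P2RY6 (0.61) and ADORA2B (0.48), the prostaglandin receptor PTGER4, for which a further probe set gave -0.02, and the oxysterol receptor GPR183. The family was defined because these genes had been noticed, so whether receptors rose more often than other genes was not tested. Among the receptors not called, PTAFR, the platelet-activating factor receptor, was at 0.41 (limma adjusted p = 0.0841) and LPAR2, a lysophosphatidic acid receptor, at -0.25 (limma adjusted p = 0.266).

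TXNIP, CCNG2 and FBXO32 are textbook targets of FOXO transcription factors, and all 3 were called lower. FBXO32 lay below the array median and was called in only 1 of its 13 alternatives, so its fall is uncertain. A hypothesis is that FOXO targets could have fallen together. Over a list of 25 FOXO targets camera gave an adjusted p = 0.275. Without those first noticed, the other 22 had a median of 0.03 and camera gave an adjusted p = 0.717 (adjusted over these 2 tests). The proapoptotic target BCL2L11 was at 0.44 (limma adjusted p = 0.0764) and RICTOR at -0.27 (limma adjusted p = 0.140). The shorter list leaves out the members that were called, so it decides nothing by itself, and the hypothesis stays open.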
